A study of Homo sapiens with 6 samples.

How the data were processed

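The study silenced Sam68 (gene symbol KHDRBS1), a STAR-family RNA-binding protein, or XRN2, the nuclear 5'-to-3' exonuclease that takes part in transcription termination, in LNCaP cells. LNCaP is an androgen-sensitive human prostate cancer cell line. Per the labels' protocols, cells received 50 nM small interfering RNA in repeated transfections over 48 hours, and control cells received a scrambled one. The 6 libraries form 3 groups of 2 biological replicates, named here siCTRL, siSAM68 and siXRN2. Libraries were made by 3'READS, which sequences the last part of polyadenylated transcripts and so locates the cleavage and polyadenylation site. Per the labels' protocols, RNA was captured on oligo(dT) beads, fragmented with RNase III, ligated to a 5' adapter, and freed of most of its poly(A) tail with RNase H before the 3' adapter was ligated.

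Read trimming with cutadapt, alignment with Bowtie2 and the hg19 build are named per the submitters' processing notes, and the versions are not given in the sources used here. The gene annotation, the treatment of reads that map to several places and the filters behind the tables are not given either. The authors deposited 1 table of gene expression and 1 table of polyadenylation sites. The gene table lists 1944 genes, and the site table lists 4903 sites of 3118 genes, of which 506 genes are in both tables. The authors' RPM values are given per library with 1 decimal, per the file headers. Within a group both libraries share the same smallest step, 0.492 RPM for siCTRL, 0.238 RPM for siSAM68 and 0.157 RPM for siXRN2. The deposited RPM is therefore scaled to the reads of both libraries of a group together, so within a group it grows with the depth of the library. Site usage is deposited as a percent, the share of a gene's reads that fall on a site in a library, per the file headers and the values. The authors' deposited score, a signed significance value per gene or site and comparison, has no definition in the sources used here. The authors' deposited log2 ratio and difference of usage are coded control minus knockdown, which was checked against the values per library.

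Both tables are selected lists. In the authors' deposited tables, 81.2% of sites and 67.3% of genes have a score of at least 1.3 in size in at least 1 comparison, and the rule by which the others were included is not stated. Percentages of changed genes or sites below hold for these lists and not for the transcriptome. Benjamini-Hochberg adjustment ran over the listed genes or sites only. As most of these pass the authors' score in the same libraries, the limma adjusted p-values below can be too small. XRN2 is not among the genes of the gene table, so its knockdown was not analysed here, and KHDRBS1 is not among the genes of the site table.

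The site table gives each site a type code and the polyadenylation signal near it. F, M and L were read as the first, middle and last site of a 3' UTR with several sites, since in 1110 of 1110 genes with at least 2 of them they follow each other in this order along the strand. S was read as the only 3' UTR site, Ic and Is as intronic and E as exonic. No source used here defines the codes. Positions are hg19 coordinates as the table gives them, and no reference of that build was used here. Transcript length and GC content came from GENCODE v29 transcripts, with no coordinates taken from it. Genes were matched by the deposited RefSeq transcript identifier and, where that failed, by gene symbol with the longest transcript.

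Each library's RPM was rescaled so that its listed genes sum to the listed total of both libraries of its group added together. This puts every library on the summed RPM of its group and removes the difference in depth between the libraries of a group. Expression was tested on log2(RPM + 1) for the 1938 genes with a mean of at least 1 RPM. Fold changes are on that scale and understate the change of low genes. Site usage was tested on log2(percent + 1) for the 4866 sites with a mean usage of at least 1%. For genes with at least 2 sites of types F, M and L, the 2 most used sites formed a proximal and distal pair, tested as log2((distal + 1) / (proximal + 1)) for 1101 pairs. All tests used limma 3.58.1 in R 4.3.3 with empirical Bayes moderation, all 3 groups in 1 fit and a mean-variance trend for genes and sites. An adjusted p under 0.05 was the threshold. The split of calls into directions was compared with an equal split by an exact two-sided binomial test. It ran over sites for site types and over genes for pairs, and neither are independent replicates. Sites of the same gene share a total, so their directions depend on each other. Figures were drawn with matplotlib 3.10.9.

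The plan written before the data were examined assumed whole-read counts for the main test. The tables hold RPM and percent, so no count test was run. The RPM steps give the approximate reads behind each gene, and these describe depth only. Usage of a site is known with its depth for genes in both tables only. There, 638 of 847 sites give a whole number of reads in every library within the rounding of the percent to 2 decimals.

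Lists of genes were fixed before the data were examined: 14 lists of 260 gene entries, of which 80 were in the gene table. Entries were matched by current symbol, and an older symbol was accepted where it belongs to no other gene. Lists with at least 3 measured genes were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, with adjustment over the 10 lists of a comparison. The genes named in the text follow a rule fixed at the same time. It names KHDRBS1 and XRN2, and the 10 largest rises and falls among genes past the threshold, changed the same way in both replicates and at or above the median level. It skips, among these rises and falls, genes with only a LOC number for a symbol. It further names the 8 largest moves to each end of a site pair, up to 8 intronic sites per direction, up to 4 changed members per list, and the 5 largest expression changes among genes past the threshold in both tables. List members named beyond these, among them uncalled ones such as E2F1 and CDKN1A, were chosen after their values were seen, and some results that fall under the rule are not reported here.

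Each step was tested on simulated data with known changes in 50 genes, sites or pairs per fold size. For the siSAM68 comparison, expression calls recovered 20% of 1.5-fold, 62% of 2-fold and 98% of 4-fold changes among 1927 genes. For siXRN2 the shares were 24%, 84% and 98% among 1923 genes. Site usage calls recovered 22% of 2-fold and 98% of 4-fold changes for siSAM68, and 24% and 100% for siXRN2, among 4866 sites. Pair calls recovered 78% of 4-fold changes for siSAM68 and 76% for siXRN2 among 1101 pairs. The site and pair simulations gave all sites the same spread and did not simulate read depth, and simulated pairs were built on single-site means. Their shares can therefore overstate the recovery at real sites, which differ in depth. Of unchanged genes, 0.521% were called in the siSAM68 simulation and 0.871% in the siXRN2 simulation.

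Alternatives covered scaling, pseudocounts, filters on low values, percent and arcsine scales, the replicate number as a block, fits on 2 groups, stricter thresholds and each library left out in turn. Comparisons against the shared controls were set beside 100 simulations of unchanged groups. Groups of 2 allow no test for single outlying samples.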

Results

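Polyadenylated RNA 3' ends were profiled in 6 libraries of LNCaP cells, 2 each after control (siCTRL), Sam68 (siSAM68) or XRN2 (siXRN2) silencing. The design asks how loss of Sam68 or XRN2 changes the choice of polyadenylation sites and the expression of genes, with cell cycle progression as the wider theme. The control libraries were the shallowest. Reads in the listed genes numbered 244708 and 447363 in siCTRL, 674072 and 788203 in siSAM68, and 597911 and 1599559 in siXRN2. Replicates correlated across genes with Pearson's r of 0.969 in siCTRL, 0.984 in siSAM68 and 0.973 in siXRN2, over genes that are not independent replicates. The first principal component of expression held 61.5% of the variance and placed siCTRL at -25.1 and -17.0, siXRN2 at 3.68 and 7.47, and siSAM68 at 15.0 and 15.9. At a site's level depth was thin, with 797 and 544 of the listed sites at 0 in the siCTRL libraries against 530 and 196 in siXRN2.

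KHDRBS1, which encodes Sam68, fell after siSAM68 from 671 ± 99 RPM (SD, n = 2) in siCTRL to 40.6 ± 18.6 RPM (SD, n = 2). The change was 16.9-fold, with a log2 change of -4.08 (SE 0.28; limma adjusted p = 7.88e-07). After siXRN2 its level was 731 ± 232 RPM (SD, n = 2), a log2 difference of 0.09 (SE 0.28; limma adjusted p = 0.821). XRN2 expression was not analysed here. At the first 3' UTR site of XRN2 (hg19 chromosome 20, position 21370087), usage was 16.5 ± 10.5% (SD, n = 2) in siCTRL, 16.3 ± 12.4% in siSAM68 and 3.85 ± 5.44% in siXRN2, which is no measure of XRN2 level.

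After Sam68 silencing, the largest rises included CYC1 and PARK7, and the largest fall after KHDRBS1 by the naming rule was in MMAB. LOC644961, which the rule skips, fell further, with a log2 change of -2.17. CYC1, cytochrome c1 of respiratory complex III, rose 3.58-fold from 264 ± 38.8 to 941 ± 25.7 RPM (SD, n = 2; log2 1.84, SE 0.18, limma adjusted p = 4.04e-05). PARK7, the oxidative stress protein DJ-1, rose 3.13-fold from 831 ± 145 to 2585 ± 37.2 RPM (log2 1.65, SE 0.19, limma adjusted p = 1.33e-04). The largest rise by the naming rule was in C7orf55, a mitochondrial assembly factor, at log2 1.95, although it overlaps a readthrough gene and its reads may be shared. VDAC3, a channel of the outer mitochondrial membrane, rose by log2 1.90, and the calmodulin gene CALM2, which has near-identical copies, by 1.77. FAM96A, of iron-sulfur cluster assembly, rose by 1.71, the methionine aminopeptidase METAP2 by 1.63 and the phosphodiesterase PDE1A by 1.58. Both CAT, which encodes catalase, and the insulin-like growth factor binding protein gene IGFBP3 rose by 1.57. Among the falls were the cobalamin adenosyltransferase MMAB (-1.43), the cargo receptor LMAN2L (-1.18) and esterase D, ESD (-1.13). MARVELD1 and the protease BLMH changed by -1.12, as did the small GTPase ARF5. Limma adjusted p-values after siSAM68 lay between 7.88e-07 and 0.00679 for KHDRBS1 and these genes. Leaving out single libraries ended no call among the 10 rises, while LMAN2L, ESD and BLMH missed the threshold without siCTRL replicate 1.

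Of 1938 listed genes tested, 1139 passed the limma threshold after siSAM68, 685 higher and 454 lower, and 1012 of them changed at least 1.5-fold. Groups did not overlap in 1545 genes (79.7%). The share by chance is 33.3% for unselected genes, which is no benchmark for a list selected as this is. The median log2 change was 0.16, and the split depends on the scaling. It was 663 higher and 479 lower with upper-quartile scaling and 654 and 479 with all libraries at the same listed total. Median-of-ratios scaling, which sets the median near 0 by construction, gave 527 and 546. Changes also moved with GC content: the median log2 change was 0.34 in the 483 genes of lowest and -0.40 in the 483 of highest GC content. Without siCTRL replicate 1, siSAM68 replicate 1 or siSAM68 replicate 2, limma called 441, 487 and 344 genes.

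Cell cycle genes changed in both directions after siSAM68, where 58.8% of all tested genes were called. Of 22 G2/M and mitosis genes in the list, 6 were measured. Among these 6, 4 rose, both over all genes and adjusted over the list alone. Such counts do not by themselves set the cell cycle lists apart from the other genes. CCNB1, cyclin B1, rose 1.99-fold from 270 ± 29.5 to 536 ± 55.2 RPM (SD, n = 2; limma adjusted p = 0.00245). The mitotic kinesin KIF20A rose by log2 1.42, the spindle protein NUSAP1 by 0.82 and the chromosomal passenger BIRC5, or survivin, by 0.79. Of 8 genes of the G1/S transition, CDK2 rose by 0.85, while cyclin D3, CCND3 (-0.56), and MYBL2 (-0.55) fell, and the same 3 passed when adjusted over the list alone. E2F1 stood at log2 -0.52 and missed the threshold (limma adjusted p = 0.0816). Among 13 DNA replication genes, MCM6 of the replicative helicase (1.31) and the ribonucleotide reductase subunit RRM2 (0.60) rose. MCM5 (-0.62) and the polymerase subunit POLD1 (-1.28) fell, and 2 of these 4 passed when adjusted over the list alone. In the list of CDK inhibitors and p53 targets, 3 of 6 passed, also when adjusted over the list alone. CDKN1B, the inhibitor p27, rose 1.99-fold from 53.8 ± 13.2 to 106 ± 6.51 RPM (limma adjusted p = 0.00636), FAS rose by 1.58, and TP53I3 changed by -1.51. CDKN1A, the inhibitor p21, was at 1024 ± 239 and 1176 ± 18.6 RPM (limma adjusted p = 0.373). CCNB1, MCM6 and TP53I3 kept their calls whichever library was left out, while CDK2, CCND3 and MYBL2 lost them without siCTRL replicate 1. Without siSAM68 replicate 2, KIF20A, NUSAP1, BIRC5, CDKN1B, FAS, MCM5 and RRM2 lost theirs, and POLD1 did so without siCTRL replicate 2 or siSAM68 replicate 1.

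Androgen-responsive genes went both ways after siSAM68, with 5 of 19 past the threshold and 1 when adjusted over the list alone. KLK3, which encodes prostate-specific antigen, fell from 1246 ± 247 to 742 ± 352 RPM (SD, n = 2; log2 -0.82, limma adjusted p = 0.0256), and KLK2 fell by 0.88 on the log2 scale. SPDEF changed by -0.51, while STEAP2 (0.74) and ADAM7 (0.99) rose. The calls of KLK3, KLK2, STEAP2 and ADAM7 all ended without siCTRL replicate 1, and again without siSAM68 replicate 2. RNA-binding proteins passed in 7 of 8 cases, KHDRBS1 included, as they did when adjusted over the list alone. SRSF1 (0.83), U2AF2 (0.70) and NONO (0.67) rose, while PTBP1 (-0.55), ELAVL1 (-0.48) and HNRNPC (-0.48) fell. SPDEF, PTBP1, ELAVL1 and HNRNPC lie outside the naming rule, were chosen after their values were seen and were not followed with libraries left out. Of 3 measured cleavage and polyadenylation factors, RBBP6 rose 1.80-fold from 73.0 ± 10.8 to 132 ± 1.09 RPM (limma adjusted p = 0.00744), and it alone passed over the list as well. Stress genes rose in 3 of 7 cases, the transcription factors ATF3 (0.65) and XBP1 (0.68) and the chaperone DNAJB9 (1.25), and TRIB3 fell (-0.44), all 4 also when adjusted over the list alone. In lipid synthesis, SREBF1 rose (0.75) and SCD fell (-0.50) among 3 genes, with the same count of 2 adjusted over the list alone. Of 5 genes in the ribosomal protein list, RPL5 (0.56), RPL13A (0.45), RPS27A (0.59) and TPT1 (0.87) rose, and all 5 passed when adjusted over the list alone, EEF2 lower. Without siSAM68 replicate 2, none of RBBP6, SRSF1, U2AF2, NONO, ATF3, XBP1, DNAJB9, TRIB3, SREBF1, SCD, TPT1, RPS27A, RPL5 and RPL13A kept its call. RBBP6, SREBF1 and SCD also lost theirs without siCTRL replicate 1 or siSAM68 replicate 1. With median-of-ratios scaling RPL5, RPL13A, RPS27A, ADAM7 and ATF3 stayed above 0 but missed the threshold, as did RRM2 of the replication genes. None of the 2 interferon response genes passed, in either adjustment. The lists of exonucleases and termination factors, of stromal, endothelial and immune markers and of neuroendocrine markers had 0 measured genes.

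No list differed from the other genes as a set after siSAM68 by camera. The lowest camera adjusted p was 0.615 and belonged to the G2/M list, and the lowest with an estimated correlation was 0.953. Fry, which tests a list against no change, gave a lowest adjusted p of 0.0974. Fry's mixed test, which asks whether members change in either direction, gave adjusted p = 0.0027 for the CDK inhibitors and p53 targets and 0.00428 for the RNA-binding proteins, KHDRBS1 among them. It also passed for lipid synthesis (0.00492), cleavage factors (0.0102), G2/M (0.022) and ribosomal proteins (0.022), where 58.8% of all tested genes were called. Most listed genes pass the authors' score in these same libraries, so the measured members were already selected for change. Passing the mixed test therefore does not single out a list.

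After XRN2 silencing the largest rises again included VDAC3, C7orf55 and CYC1. VDAC3 rose 3.78-fold from 27.5 ± 0.236 to 113 ± 53.2 RPM (SD, n = 2; log2 1.92, SE 0.29, limma adjusted p = 0.00354). CYC1 rose 2.54-fold to 668 ± 44.7 RPM (log2 1.34, SE 0.18, limma adjusted p = 0.00202). PCBP1, an intronless gene for a poly(C)-binding protein with related copies, fell from 191 ± 0.4 to 87.1 ± 7.24 RPM (log2 -1.12, SE 0.20, limma adjusted p = 0.00735). EPB41, a membrane skeleton protein, fell from 262 ± 38.8 to 111 ± 62.9 RPM (log2 -1.35, SE 0.30, limma adjusted p = 0.00929). C7orf55 rose by log2 1.91 with the same reservation on shared reads, and UFD1L, of ubiquitin-dependent degradation, by 1.56. TOM1L2 rose by 1.41, METAP2 by 1.32, CALM2 by 1.3, the malate dehydrogenase MDH1 by 1.29, and GSTK1 and BRI3 by 1.28. Falls included the phosphatase subunit SMEK1 (-1.33), MMAB (-1.31), ESD (-1.24), the lipid kinase PIK3C2A (-1.21) and MANEAL (-1.15). The proteasome subunit PSMA5 and the transcription factor ZBTB16 changed by -1.08 each. Limma adjusted p-values of these genes lay between 0.00202 and 0.0358. Without siCTRL replicate 1, 12 of the 20 largest changes by the naming rule kept their calls, and 17 did so without siCTRL replicate 2 or without siXRN2 replicate 2.

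Limma called 646 of the 1938 genes after siXRN2, 411 higher and 235 lower, of which 602 changed at least 1.5-fold. Groups did not overlap in 1273 genes (65.7%), where the 33.3% by chance of unselected genes is again no benchmark for the selected list. With median-of-ratios scaling, which centres the median by construction, 344 genes were higher and 303 lower. Without siCTRL replicate 1, siCTRL replicate 2 or siXRN2 replicate 2, the counts were 199, 366 and 391.

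Cell cycle genes passed in different shares of their lists after siXRN2, beside 33.3% of all tested genes. MCM6 rose 2.16-fold from 31.4 ± 7.22 to 69.9 ± 22.0 RPM (SD, n = 2; limma adjusted p = 0.0147), the only 1 of 13 replication genes to pass in either adjustment. In the G2/M list 3 of 6 passed, with CCNB1 (0.54) and NUSAP1 (0.73) higher and CCNB2, cyclin B2, lower (-0.68), and all 6 passed when adjusted over the list alone, 5 of them higher. The CCNB1 call ended with median-of-ratios scaling. CDK2 rose (0.74) and E2F3 fell (-0.76) among 8 G1/S genes, with the same count of 2 adjusted over the list alone. TP53I3 was the only CDK inhibitor or p53 target of 6 to pass, at -1.07, in both adjustments. None of 19 androgen-responsive genes passed in either adjustment by limma, with KLK3 at 995 ± 304 RPM (adjusted p = 0.364). Of the cleavage and polyadenylation factors, CPSF1 rose 2.14-fold from 12.7 ± 1.7 to 28.5 ± 6.97 RPM (limma adjusted p = 0.0248) and CSTF3 fell from 174 ± 27.9 to 108 ± 3.32 RPM (limma adjusted p = 0.0228), also when adjusted over the list alone. Most CSTF3 reads ended at its intronic site (position 33162977), 94.9 ± 2.17% in siCTRL and 87.8 ± 1.02% in siXRN2. The fall therefore does not show a loss of CSTF3 transcripts that end in the 3' UTR. ELAVL1 and HNRNPC fell (-0.63 each) and U2AF2 rose (0.71) among 8 RNA-binding proteins, of which 4 passed when adjusted over the list alone. Of the stress genes HERPUD1 passed (-0.66), and 3 of 7 did when adjusted over the list alone. Both interferon response genes passed in either adjustment, in opposite directions, IFI6 at 1.47 and IFI44 at -1.14. None of the 3 lipid synthesis genes passed in either adjustment. RPL5 (0.63), RPS27A (0.98) and TPT1 (0.91) rose among the 5 genes of the ribosomal list, and 4 did when adjusted over the list alone. Each of these calls was lost without siCTRL replicate 1 or without siCTRL replicate 2, those of TP53I3, CPSF1, E2F3, NUSAP1, CCNB1, IFI44 and HERPUD1 without either. Against the other genes, the lists gave camera adjusted p-values of 0.317 or more, and at least 0.971 with an estimated correlation. Against no change, fry gave adjusted p-values of at least 0.0813. Fry's mixed test gave adjusted p = 2.67e-04 for the RNA-binding proteins, 0.0119 for the CDK inhibitors and p53 targets, 0.022 for lipid synthesis, 0.0244 for ribosomal proteins and 0.0473 for G2/M, where 33.3% of all tested genes were called. Because the listed genes were selected in these same libraries, passing the mixed test again does not single out a list.

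After siSAM68, last 3' UTR sites past the threshold more often gained than lost usage, as called sites of all types together did. BIRC5 used its middle site (hg19 chromosome 17, position 76220780) for 53.2 ± 1.87% of reads in siCTRL and 78.0 ± 0.771% in siSAM68 (SD, n = 2; limma adjusted p = 0.0237), at 79 to 569 reads per library. This site lies upstream of the last BIRC5 site (position 76221716), which stood at 7.8 ± 0.304% and 2.43 ± 0.453% (limma adjusted p = 0.0696), so BIRC5 does not follow the last sites. RBBP6, a cleavage and polyadenylation factor, used its single 3' UTR site (chromosome 16, position 24584184) for 40.9 ± 3.61% and 75.2 ± 6.39% (limma adjusted p = 0.0352). CSTF3, a subunit of the cleavage stimulation factor, used its intronic site (chromosome 11, position 33162977) less, at 94.9 ± 2.17% against 78.2 ± 4.68% (limma adjusted p = 0.0433). Its 3' UTR site (position 33106130) went from 5.13 ± 2.17% to 21.8 ± 4.68% (limma adjusted p = 0.0464). PAPOLA, the canonical poly(A) polymerase, used its last site (chromosome 14, position 97033453) for 8.14 ± 0.0495% and 26.8 ± 4.94% (limma adjusted p = 0.0411). The last site of XRN2 (chromosome 20, position 21370463) was listed at 0 in both siCTRL and both siXRN2 libraries and at 15.4 ± 6.57% in siSAM68 (limma adjusted p = 0.0269).

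In the other lists, a middle site of the replication factor MCM10 (chromosome 10, position 13251840) rose from 9.3 ± 2.55% to 31.1 ± 4.54% (SD, n = 2). The last site of OAS3, an interferon-induced enzyme, (chromosome 12, position 113411056) rose from 39.3 ± 5.06% to 67.3 ± 8.08%. PTBP2 used its middle site (chromosome 1, position 97280349) for 87.1 ± 2.49% and 99.2 ± 1.09%, and its first site (position 97280116) for 11.7 ± 0.771% and 0.77 ± 1.09%. PTBP2 had 9 and 41 reads in the siCTRL libraries, so its first site there rests on few reads. A middle site of MDM2, the p53 antagonist, (chromosome 12, position 69236400) was listed at 0 in siCTRL and at 7.12 ± 4.07% in siSAM68. Limma adjusted p-values of these sites lay between 0.0422 and 0.0496. No site passed in the G1/S, androgen, stress or ribosomal lists, with 5, 15, 3 and 2 sites tested.

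**Figure D1:**
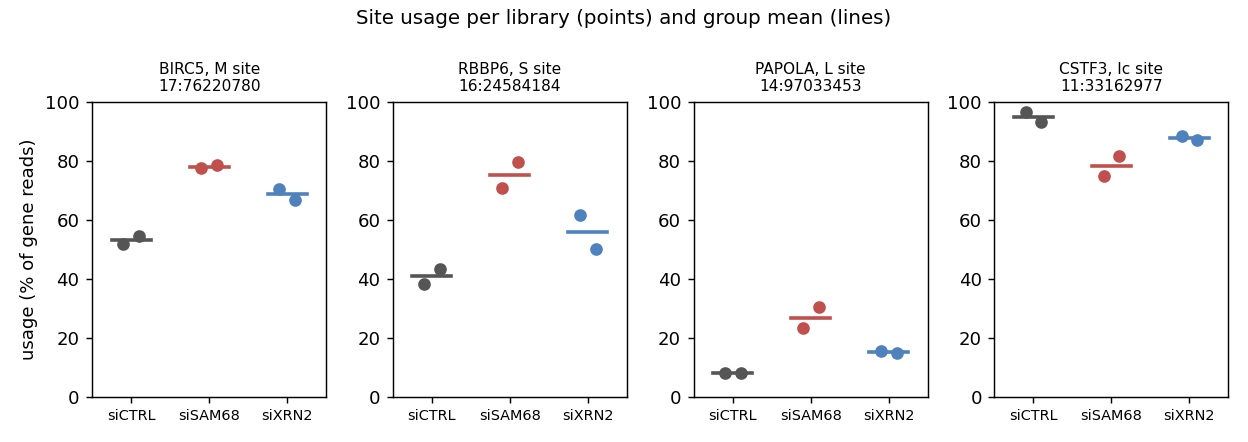
Usage of 4 sites in percent of the gene's reads (vertical axis) in BIRC5, RBBP6, PAPOLA and CSTF3, with 1 point per library and a line at each group mean for siCTRL, siSAM68 and siXRN2. In siSAM68 the BIRC5 site averages 78.0% against 53.2% in siCTRL, and the intronic CSTF3 site averages 78.2% against 94.9%.

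Over all 4866 sites, limma called 712 after siSAM68, 422 with higher and 290 with lower usage. Last 3' UTR sites were higher in 114 and lower in 56 cases (67.1% higher, exact binomial p = 1.02e-05), middle sites in 143 and 92 (60.9% higher, exact binomial p = 0.00106), and first sites in 61 and 56 (exact binomial p = 0.712). Higher usage prevailed over all types together (59.3%), so the test against an equal split does not by itself single out last sites. On the percent scale 355 sites of all types were higher and 338 lower, and last sites split 115 to 63 (exact binomial p = 1.19e-04). Intronic sites were higher in 82 and lower in 73 (exact binomial p = 0.521). In genes with a mean of at least 20 reads, a choice made after seeing the data, 59 last sites were higher and 20 lower, while 30 first sites were higher and 50 lower (exact binomial p = 0.033). Counts of sites depended on single libraries, with 0 calls without either siSAM68 library and 232, 446 and 440 without siCTRL replicate 1, siXRN2 replicate 1 and siXRN2 replicate 2.

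**Figure D2:**
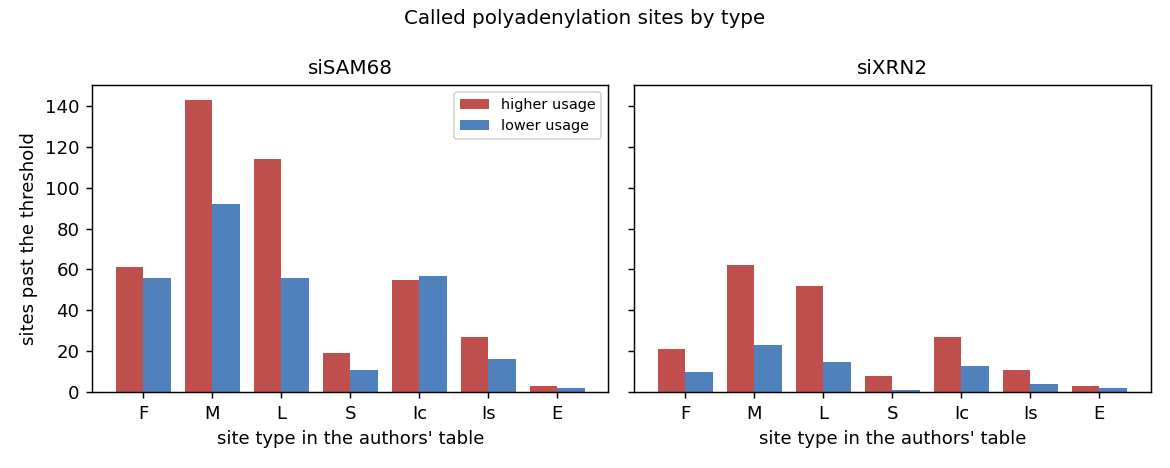
Number of polyadenylation sites past the limma threshold (vertical axis) by site type in the authors' table, with higher usage in red and lower usage in blue, for siSAM68 and siXRN2 against siCTRL. Last sites (L) split 114 to 56 in siSAM68 and 52 to 15 in siXRN2.

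Pairs of proximal and distal 3' UTR sites moved both ways after siSAM68, with more moves to the distal end. TNFAIP3, an inhibitor of NF-kappaB signalling (chromosome 6), had its distal site (position 138204447) listed at 0 in siCTRL and at 75.6 ± 4.76% in siSAM68 (SD, n = 2; limma adjusted p = 0.00353). FAF1 (chromosome 1) had its proximal site (position 50906601) at 8.76 ± 1.07% in siCTRL and listed at 0 in siSAM68, while the distal site rose from 2.0 ± 2.83% to 28.2 ± 0.559% (limma adjusted p = 0.0198). The other large moves to the distal site were in HEG1, GORASP1, ZDHHC17, GEMIN8P4, BLCAP and TTC7A. In the opposite direction, ZNF555 (chromosome 19) raised its proximal site (position 2854027) from 26.7 ± 9.43% to 82.9 ± 8.46%, and its distal site was listed at 0 in siSAM68 (limma adjusted p = 0.0183). KIF5C, EXOC8, USP32, ZNF354B, ZNF224, CCNB1IP1 and RAB39B followed. HEG1 and CCNB1IP1 had values in 1 control library only, and ZNF354B in 1 siSAM68 library. Depth is unknown for the genes of these pairs. Of 1101 pairs, limma called 430, with 244 distal and 186 proximal moves (56.7% distal, exact binomial p = 0.00592). Without siCTRL replicate 1 the split was 23 distal and 28 proximal, without siSAM68 replicate 2 it was 21 and 18, and without siSAM68 replicate 1 no pair was called. Without either siXRN2 library it was 79 distal and 58 proximal (exact binomial p = 0.0871).

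Intronic sites with the largest gains after siSAM68 lay in IQCH, SIPA1L1, ALPK2, IQCD, LCA5, PCNXL2, CD274 and NUBPL, and all were listed at 0 in siCTRL, NUBPL in the 1 control library with a value. The site in CD274, which encodes the immune checkpoint ligand PD-L1, (chromosome 9, position 5463331) stood at 50.0% in both siSAM68 libraries (limma adjusted p = 0.0091). That in LCA5 (chromosome 6, position 80217754) reached 71.7 ± 16.5% (SD, n = 2; limma adjusted p = 0.00821). ALPK2 rested on 2 to 7 reads per siCTRL or siSAM68 library, and depth is unknown for the other genes. Sites in ZNF503-AS2, SLC23A1, MOSPD3, CDADC1, PPP2R2C, CLCN2, GPR155 and PRDM2 were listed at 0 in siSAM68. Of these, the site in CDADC1 (chromosome 13, position 49844112) had 45.0 ± 7.07% in siCTRL (limma adjusted p = 0.0204).

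After siXRN2, last 3' UTR sites again gained more often than they lost. OAS3 raised the same last site to 72.4 ± 6.48% (SD, n = 2; limma adjusted p = 0.0466), and MCM10 the same middle site to 37.1 ± 7.09% (limma adjusted p = 0.0463). In the other lists no site passed after siXRN2. BIRC5 stood at 68.6 ± 2.69% for its middle site (limma adjusted p = 0.0593). Limma called 252 of 4866 sites, 184 higher and 68 lower. Higher usage made up 73.0% over all types. Last sites split 52 to 15 (77.6% higher, exact binomial p = 6.46e-06), middle sites 62 to 23 (exact binomial p = 2.77e-05), first sites 21 to 10 (exact binomial p = 0.0708) and intronic sites 38 to 17 (exact binomial p = 0.00646). On the percent scale limma called 24 sites, 11 higher and 13 lower, with 2 last sites higher and 2 lower, and on the arcsine scale 51, 29 higher and 22 lower. The intronic split was 1 to 4 on the percent scale, 4 to 5 on the arcsine scale, 7 to 10 in genes with at least 20 reads and 19 to 16 with a pseudocount of 5 (exact binomial p = 0.736). At an unadjusted p under 0.05, 140 intronic sites were higher and 176 lower. A fit on the siCTRL and siXRN2 libraries alone called 0 sites, with 1586 at an unadjusted p under 0.05. With the replicate number as a block, the fit on all libraries also called 0 sites. No site passed without siXRN2 replicate 1, siXRN2 replicate 2 or siSAM68 replicate 2, and 137, 386 and 47 passed without siCTRL replicate 1, siCTRL replicate 2 and siSAM68 replicate 1, against 1875 at an unadjusted p under 0.05 with all libraries.

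Site pairs after siXRN2 included LSM12 (chromosome 17), whose proximal site (position 42113097) went from 19.1 ± 1.29% (SD, n = 2) to a listed 0. Its distal site (position 42111696) went from a listed 0 to 20.3 ± 0.361% (limma adjusted p = 0.00474). SLC10A7 (chromosome 4) moved the same way, its distal site (position 147176084) going from a listed 0 to 20.2 ± 1.2% (limma adjusted p = 0.02). HEG1, FARP1, ADRBK2, ZNRF3, LPAR3 and ZNF566 were the other large moves to the distal site. LEMD3 (chromosome 12), an inner nuclear membrane protein, moved to the proximal site (position 65641042), listed at 0 in siCTRL and at 22.6 ± 0.608% in siXRN2 (limma adjusted p = 0.0335). ZNF354B, CCNB1IP1, ZNF224, C8orf37, PTER, CNTNAP2 and LOC387647 followed. LPAR3 had 2 to 37 reads per library, and depth is unknown for the others. Limma called 170 of 1101 pairs, 96 distal and 74 proximal, a split that did not differ from equal (56.5% distal, exact binomial p = 0.107), although it did without siCTRL replicate 2, at 101 and 73 (exact binomial p = 0.0404). The split was 3 to 3 without siCTRL replicate 1, 11 to 8 without siXRN2 replicate 2 and 28 to 21 without either siSAM68 library, and 1 pair passed without siXRN2 replicate 1. Among intronic sites, those in IQCD, SIPA1L1, IQCH, PCNXL2, FHOD3, KCTD1, LCA5 and ARHGAP26 gained from a listed 0. KCTD1 (chromosome 18, position 24124936) reached 37.0 ± 2.37% (SD, n = 2; limma adjusted p = 0.0118). SLC23A1, CLCN2, KCTD3, ETV6, FLJ37453, UPF3A and MAN1A2 lost intronic usage, with KCTD3 (chromosome 1, position 215781688) going from 35.4 ± 2.95% to a listed 0 (limma adjusted p = 0.0141).

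Some genes changed in both expression and site usage. Of 505 genes tested in both tables, 62 passed in both after siSAM68. For expression alone, 58.8% of all tested genes passed after siSAM68 and 33.3% after siXRN2. Genes can therefore pass in both without a link between the changes, and such a link was not tested. IGF2R, the receptor for insulin-like growth factor 2 and mannose 6-phosphate, rose in expression from 25.2 ± 4.11 to 109 ± 4.55 RPM (SD, n = 2; limma adjusted p = 2.41e-04). Its middle site (chromosome 6, position 160527583) rose from 52.0 ± 2.86% to 86.0 ± 0.276% (limma adjusted p = 0.0213). INO80C, of the INO80 chromatin remodeller, rose by log2 1.65 and its last site (chromosome 18, position 33048297) from 22.6 ± 0.608% to 60.5 ± 4.45% (limma adjusted p = 0.0238). INO80C had 9 and 13 reads in the siCTRL libraries, so its usage there rests on few reads despite the small SD. DBF4, the activator of the CDC7 replication kinase, rose by 1.94, TMEM188 by 2.75 and LOC645513 by 1.96, on 0 to 9 reads per control library. After siXRN2, 10 genes passed in both, led by CCDC97 (1.71), SHB (1.57), INO80C (1.34), SCAMP2 (1.24) and IFNAR2 (1.19). The siCTRL libraries held only 5 and 16 reads of CCDC97, 8 and 10 of SHB, and 10 and 11 of IFNAR2. SCAMP2, a secretory carrier protein, moved to its last site (chromosome 15, position 75136071) from 56.4 ± 5.11% to 90.6 ± 3.82% (SD, n = 2; limma adjusted p = 0.0292). Without siSAM68 replicate 1 or siSAM68 replicate 2 these counts fall to 0 after siSAM68, and without siXRN2 replicate 1, siXRN2 replicate 2 or siSAM68 replicate 2 to 0 after siXRN2, as limma then called 0 sites. After siXRN2, so did a fit on the siCTRL and siXRN2 libraries alone and a fit with the replicate number as a block.

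Expression changes after the knockdowns overlapped. With limma, 1139 genes passed after siSAM68 and 646 after siXRN2, of which 457 passed in both comparisons in the same direction, 341 higher and 116 lower, and 0 in opposite directions. Independent lists of these sizes would share 145 rises and 55.1 falls, and simulated unchanged groups against the same controls shared a mean of 0. Log2 changes correlated across genes with Pearson's r of 0.806 and a Spearman correlation of 0.817, against a mean r of 0.502 in the simulations. Their covariance was 0.447, against a mean of 0.0424 and a maximum of 0.0496 in the simulations. Part of the excess of shared calls over either value can come from the shared controls. The simulations also leave out the selection of the listed genes, most of which pass the authors' score in these same libraries. With the controls split, 1 library for each comparison, 78 or 156 genes were shared, with covariances of 0.345 and 0.422 and r of 0.540 and 0.715. At the site level 197 sites passed in both comparisons in the same direction, 169 higher and 28 lower, against 16 and 4.06 for independent lists and a simulated mean of 0.02. No site was shared without siSAM68 replicate 1, siSAM68 replicate 2, siXRN2 replicate 1 or siXRN2 replicate 2, since at least 1 of the comparisons then had 0 limma calls. For pairs the number was 134, 76 distal and 58 proximal, against 21.3 and 12.5 for independent lists and a simulated mean of 0.01. Without siCTRL replicate 1, siSAM68 replicate 1 or siSAM68 replicate 2, 117, 206 and 163 genes were shared, and without siXRN2 replicate 1 518 were shared and 8 were opposite.

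**Figure D3:**
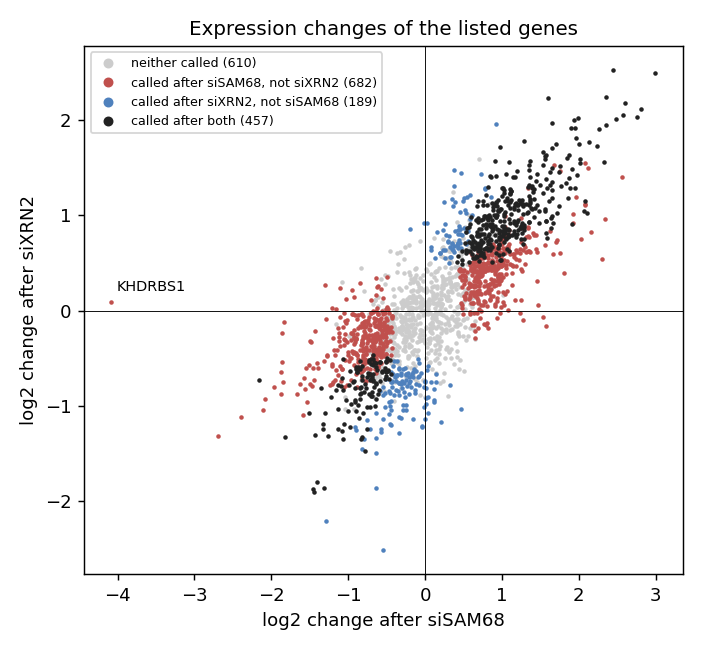
Log2 change of each of 1938 genes after siSAM68 (horizontal axis) and after siXRN2 (vertical axis), coloured by the comparisons in which limma called it. The 457 genes called after both lie in the quadrants of equal sign, and KHDRBS1 stands apart at -4.08 and 0.09.

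Set against each other, the knockdowns differed in 3 genes by limma, KHDRBS1, EDEM1 and LOC644961, with 444 genes at an unadjusted p under 0.05. No single site passed this direct test, with 642 at an unadjusted p under 0.05, and 4 site pairs did, in EXD2, MARCKS, ZNF557 and ZNF566. EDEM1, which takes part in the degradation of misfolded glycoproteins, was at 63.8 ± 19.4 RPM (SD, n = 2) in siCTRL, 86.4 ± 1.47 in siSAM68 and 30.3 ± 7.07 in siXRN2. Its log2 change after siSAM68 exceeded that after siXRN2 by 1.50 (SE 0.27; limma adjusted p = 0.0462). LOC644961, a long noncoding RNA, was at 217 ± 80.7 RPM in siCTRL, 46.1 ± 6.36 in siSAM68 and 126 ± 15.8 in siXRN2 (limma adjusted p = 0.0462).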

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

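The restriction to pairs above 0 in every library and that to pairs with a listed signal were chosen after the data were examined. Direct tests between the knockdowns singled out 7 results. KHDRBS1 expression differed between siSAM68 and siXRN2 by -4.17 on the log2 scale (limma adjusted p = 5.75e-07), as it is the target of siSAM68. LOC644961 differed by -1.44 (log2 changes of -2.17 and -0.73) and EDEM1 by 1.50 (0.46 and -1.04), each with a limma adjusted p of 0.0462. The ratio of distal to proximal usage differed by -3.33 in EXD2, whose distal site was listed at 0 in siSAM68 and at 8.04% in siXRN2 (limma adjusted p = 0.0464). It differed by 5.04 in MARCKS and by 3.42 in ZNF557 (limma adjusted p = 0.0464 each), whose proximal sites were listed at 0 in siSAM68. In ZNF566 it differed by -6.24 (limma adjusted p = 0.0218), with a proximal site listed at 0 in siXRN2 and at 26.3% in siSAM68. Depth is unknown for these 4 pairs, and the size of each difference depends on the pseudocount.

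The first pattern is the shared direction of expression changes after both knockdowns. In 100 simulations of unchanged groups against shared controls the covariance of the changes was at most 0.0496, against 0.447 here. These simulations leave out the selection of the listed genes, most of which pass the authors' score in these same libraries. They therefore cannot exclude shared control libraries as the cause. With the controls split, 1 library for each comparison, the covariance was 0.345 and 0.422 on the same selected list. Thinning every library to 244708 listed reads, the depth of the shallowest control, left a lowest covariance of 0.444 over 20 draws, against at most 0.0838 in simulations. The median number of shared calls then was 268.5 (58.8% of 457; range 137 to 347), and 6 of 20 draws kept under 50%. Trends in transcript length and GC content are no whole cause, as 83.5% of the shared genes (380 of 455) kept both signs and calls without them. A response common to both knockdowns may remain, but effects of the control libraries themselves, such as their handling, were not tested and follow the groups.

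The second pattern is the move of 3' UTR pairs to the distal site after siSAM68. Sites missing from the shallow controls are not the whole cause, since among pairs above 0 at both sites in all 6 libraries 160 moved distally and 113 proximally (58.6%, exact binomial p = 0.00527). Sites without a polyadenylation signal could contribute, and this stays open: among pairs with a listed signal at both sites the distal share was 55.1% (exact binomial p = 0.062). The share also fell to 45.1% without siCTRL replicate 1, so an effect of that library stays open beside an effect of Sam68.

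The third pattern is the same move after siXRN2, which did not itself differ from an equal split (exact binomial p = 0.107). Missing sites and missing signals cannot be told apart from an effect of XRN2 here. Among pairs above 0 in all libraries the distal share was 54.2% (exact binomial p = 0.51), and among pairs with listed signals 54.8% (exact binomial p = 0.302).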

How the results depend on the processing

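Scalings, RPM as deposited, percent and arcsine scales, the 20-read minimum, the pseudocounts of pairs and the subsets of pairs were chosen after seeing the data. The cause of each change was not tested except where stated. With RPM as deposited, where replicates differ by depth by construction, 1 gene passed after siSAM68, 0 after siXRN2 and 0 in both, with 89 and 28 at an unadjusted p under 0.05 by limma. With 1 library left out, which assumes that a lone sample varies like the other groups, 344 to 1245 genes passed after siSAM68 and 199 to 714 after siXRN2, 117 to 518 in both, 0 to 775 sites after siSAM68 and 0 to 386 after siXRN2. The distal share of pairs then ran from 45.1% (23 distal, 28 proximal) to 58.0% after siSAM68. After siXRN2 it ran from 0% to 58.0%, where 0% rests on 1 called pair and 50.0% without siCTRL replicate 1 on 3 and 3.

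The labels number the replicates alike in each group, and whether same-numbered libraries are matched is not stated. Same-numbered libraries correlated in their deviations by 0.0763, 0.00234 and 0.181 over genes, which cannot settle it with 2 libraries per group. With the replicate number as a block, 114 sites passed after siSAM68 and 0 after siXRN2 (2106 and 1699 at an unadjusted p under 0.05 by limma), against 712 and 252, while the gene counts were 1142 and 653. Called pairs fell with the block from 244 distal and 186 proximal to 114 and 82 after siSAM68, and from 96 and 74 to 47 and 41 after siXRN2. The block also ended the calls of 1 named gene (RPL13A after siSAM68), 8 of 32 named pairs and 44 of 57 named sites. With a pseudocount of 0.1, pairs numbered 135 and 87 after siSAM68 and 41 and 31 after siXRN2, and with a pseudocount of 5 170 and 124 after siXRN2. Fits on the 2 groups compared gave 450 sites after siSAM68 and 0 after siXRN2 (1586 unadjusted), by fewer samples. In genes with at least 20 reads, 311 and 99 of 810 sites passed. After siXRN2, 407 sites passed with a pseudocount of 0.1, 24 on the percent scale and 51 on the arcsine scale.

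The distal share after siSAM68 lost its call for pairs with listed signals (55.1%, exact binomial p = 0.062). After siXRN2 it passed with intronic sites pooled (60.4%), a pseudocount of 5 (57.8%), the difference of the distal share (56.8%) and over all pairs (55.3%). Shared genes numbered 77 at an adjusted p under 0.01 and 78 or 156 with split controls. No list passed camera under any alternative run.

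Shares of higher usage moved both ways. First sites after siSAM68 had 44.9% with a pseudocount of 5, 40.2% on the percent scale, 45.9% on the arcsine scale and 37.5% with at least 20 reads, but 72.7% without siCTRL replicate 1 (exact binomial p = 0.0135) and 68.4% without siCTRL replicate 2 (exact binomial p = 1.04e-04). After siXRN2 first sites split 20 to 5 with the stricter filter (exact binomial p = 0.00408) and reached 73.3% with a pseudocount of 0.1 (exact binomial p = 3.94e-04) and 83.9% without siCTRL replicate 2 (exact binomial p = 2.57e-07). Intronic sites after siSAM68 had 49.4% with the stricter filter, 49.4% with a pseudocount of 5, 42.1% on the percent scale, 49.7% on the arcsine scale and 46.2% without siCTRL replicate 1, against 58.3% without siXRN2 replicate 1. After siXRN2, the split was equal on the percent scale for last sites (50.0%, 2 and 2) and first sites (50.0%, 1 and 1), and for first sites on the arcsine scale (50.0%, 4 and 4), while first sites had 40.0% with at least 20 reads. Intronic sites after siXRN2 had 20.0% on the percent scale (1 and 4), 44.4% on the arcsine scale, 41.2% with at least 20 reads and 50.0% without siCTRL replicate 1. KHDRBS1 after siXRN2, never past the threshold, stood at -0.0091 with RPM as deposited, -0.06 without siCTRL replicate 1 and -0.23 without siXRN2 replicate 1, and at 0.42 without siXRN2 replicate 2.

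For 101 named gene results, 1363 of 1616 alternatives kept direction and call, 250 lost the call and 3 reversed. For 32 named pairs 276 of 404 kept both and 128 lost the call, and for 57 named sites 426 of 808 kept both and 382 lost the call. Of the 276, 25 come from the subset of pairs with a listed signal, which reuses the main fit and could not change. Count-based normalisations and tests were not run for lack of counts, nor were alternatives on the authors' p-values, since values per library are given. Sites at 0 numbered 797 and 544 in the siCTRL libraries, 505 and 453 in siSAM68, and 530 and 196 in siXRN2.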

Other observations

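These values were looked at only after the data were seen, and 18 tests of pairs form 1 family. Pairs in which just 1 of the sites carries the canonical AATAAA signal moved to that site more often than away from it. After siSAM68, 139 of 212 called pairs did so (65.6%, exact binomial p = 6.84e-06, adjusted p = 1.11e-04), and after siXRN2 58 of 79 (73.4%, exact binomial p = 3.76e-05, adjusted p = 1.69e-04). Among pairs above 0 in all libraries the numbers were 92 of 134 (adjusted p = 1.12e-04) and 26 of 37 (adjusted p = 0.0516, exact binomial). The AATAAA site was the distal one in 150 of the 212 pairs. Where it was the proximal one, 37 of 62 pairs moved to it after siSAM68 (59.7%, exact binomial p = 0.162, adjusted p = 0.224) and 16 of 25 after siXRN2 (64.0%, exact binomial p = 0.23, adjusted p = 0.275).

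Several well-covered transcripts outside the naming rule, picked after their values were seen, changed site usage. MALAT1, a nuclear long noncoding RNA, used a site at hg19 chromosome 11, position 65271101 for 41.8 ± 1.46% of reads in siCTRL (SD, n = 2), 73.4 ± 2.02% in siSAM68 (limma adjusted p = 0.0147) and 70.2 ± 1.39% in siXRN2 (limma adjusted p = 0.024), at 76 to 788 reads per library. PDIA6, a protein disulfide isomerase, used its last site (chromosome 2, position 10923517) for 12.4 ± 0.863% in siCTRL and 38.1 ± 1.65% in siSAM68 (limma adjusted p = 0.0293), at 366 to 1597 reads. The nuclear exporter XPO1 used its last site (chromosome 2, position 61705069) for 45.2 ± 4.95% in siCTRL and 68.1 ± 1.32% in siSAM68 (limma adjusted p = 0.0422).

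By the score in the authors' deposited table, last 3' UTR sites were higher in 450 and lower in 310 cases after siSAM68, and first sites in 256 and 340. Intronic sites of type Ic were higher in 107 and lower in 183 cases after siSAM68 and in 86 and 198 after siXRN2, by the same score of the authors' deposited table. With limma the Ic sites past the threshold split 55 to 57 after siSAM68 and 27 to 13 after siXRN2. Genes of low and high GC content (483 each, limits 42.8% and 57.4%) separated the siSAM68 libraries from the rest. The median log2 deviation of low-GC minus high-GC genes was 0.40 and 0.46 in siSAM68, -0.38 and -0.12 in siCTRL and -0.10 and -0.32 in siXRN2. No explanation of these values was tested.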
